A study of Mus musculus with 22 samples.

How the data were processed

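Gene expression was measured in haematopoietic stem cells of the mouse fetal liver (C57BL/6J embryos, day 14.5). Per the labels' protocols, fetal liver cells were cultured on OP9-DL1, a bone marrow stromal line that expresses the Notch ligand Dll1, for 4 h or 10 h with 1 µM of a gamma-secretase inhibitor (GSI) or with its solvent, DMSO. GSI blocks the cleavage that releases the active part of Notch receptors. Stem cells were then sorted as SLAM LSK cells (lineage-negative, Sca-1 and Kit positive cells gated on SLAM family markers), RNA was isolated, and 1 sample was hybridised to each 1-colour array. The series holds 22 arrays: 7 DMSO and 7 GSI samples at 4 h, and 4 DMSO and 4 GSI samples at 10 h.

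The deposited table holds log2 expression values, made by the authors with Partek 6.6 and RMA, per the submitters' processing notes; whether the sets of both times were normalized together is not stated. The values ran from 1.83 to 13.9. The median value per array was 5.03 to 5.12 at 4 h and 4.45 to 4.52 at 10 h. Sorted values of the mean 10 h array lay a median of 0.495 from those of the mean 4 h array, against at most 0.0346 among the 4 h arrays and 0.116 among the 10 h arrays. The distributions are what RMA gives when each time is normalized on its own, so levels at 10 h and 4 h were compared only with that offset stated. Detection calls were not used here, so no limit for signal above background could be set, and the number of arrays limits the precision. The highest correlation between any pair of arrays was 0.994, and no pair shared more than 48 identical probe values, so no array was a copy of another.

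The table has 41345 probes. In the probe annotation 23521 of them had 1 gene symbol, 1814 had several and 16010 had none listed. Probes with several symbols or none were left out. For the 1082 genes with more than 1 probe the probe with the highest mean over all arrays was used, which left 22180 genes. No symbol changed when Entrez identifiers were looked up in a mouse gene table of assembly GRCm38.p6; the array's own genome build is not stated, so chromosomes and identifiers are given but no positions. No gene was removed for low signal.

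Differences were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, 2-sided, and Benjamini-Hochberg adjusted p under 0.05 over 22180 genes. All adjusted p-values for single genes come from limma. The effect of GSI at each time, its mean over both times and the difference between both times came from 1 fit to all 22 arrays, with the DMSO and GSI pair as a fixed block and 1 spread shared by all arrays. The difference between 10 h and 4 h was tested within DMSO and within GSI on 11 arrays each. The replicates behind the p-values of single genes are the biological replicates of the series' design text. That text states that each consisted of a DMSO and a GSI sample, which is the source of the pairing. As a check, the deviation of each DMSO array from its group mean was correlated with that of its own GSI partner: r was 0.223 to 0.872 at 4 h, where 6 of 7 arrays correlated best with their own partner, and 0.213 to 0.449 at 10 h, where 4 of 4 did. Codes in the sample descriptions put the 4 h pairs in 3 runs (pair 1; pairs 2 and 3; pairs 4 to 7) and the 10 h pairs in 2 (pairs 1 and 2; pairs 3 and 4). What the codes stand for is not stated. The pair block removes differences between runs, but no run holds both times, so time and run cannot be told apart.

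Before the data were examined, 26 gene lists were written down from general knowledge: Notch target genes; Notch receptors, ligands and modifiers; gamma-secretase subunits; stem cell, early T-lineage, B-lineage, erythroid, megakaryocyte, neutrophil and monocyte, and mast cell genes; genes of DNA replication, mitosis, cell cycle inhibition, p53 and apoptosis, immediate-early and stress responses, JAK-STAT feedback, interferon, inflammation and NF-kB, hypoxia and glycolysis, Myc and ribosome biogenesis, cholesterol synthesis, and amino acid and unfolded protein stress; and markers of OP9 stromal cells, hepatocytes, endothelial cells and macrophages. Each list was tested with limma's camera (preset correlation between genes of 0.01), adjusted over the 26 lists, again with an estimated correlation, and with fry. Camera compares the genes of a list with all other genes. Its p-values therefore rest on the number of genes and the preset correlation, not on the pairs alone. No list passed with an estimated correlation in any of the 6 comparisons. Counts adjusted over the list alone are given beside those over all genes.

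The genes named were set by a rule fixed beforehand. It takes the 10 largest rises and the 10 largest falls among genes that passed and moved the same way in every pair (for time, every 10 h array beyond every 4 h array). Where fewer passed, genes with the smallest p were added up to 10 in all and are said not to have passed. It also takes Hes1, Nrarp, Dtx1, Hey1, Heyl, Hes5, Notch1, Notch3 and Myc in each GSI comparison, up to 4 members with the smallest p from each list described, and the 5 genes with the smallest p for the difference between times. Gene models without a proper name, olfactory receptors and small RNAs were passed over.

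The procedure was tested on simulated data with the real means of 22180 genes. Normal noise with the residual spread of the real arrays was drawn independently for each gene. Effects shared by many genes, such as level-dependent differences within a pair, were left out, so false calls from those are not counted. The procedure was run with 200 genes changed by a log2 value of 0.5, 1 or 1.5. At 4 h it recovered 92.5%, 98.5% and 100% of them, and 7 of 201 calls were false. At 10 h it recovered 65.7%, 97.0% and 100%, but 60 of 235 calls were false, more than the adjusted p allows. With only the 10 h arrays in the fit, 37.3%, 97.0% and 100% were recovered and 14 of 170 calls were false. For the mean of both times 31 of 229 calls were false. For time within DMSO 25.4%, 74.6% and 97.0% were recovered and 7 of 138 calls were false. The median residual SD was 0.146 at 4 h and 0.173 at 10 h, so a spread shared by all arrays is too small for the 10 h arrays, and counts at 10 h are given beside those with the spread set by time.

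Alternatives planned beforehand were no pair block, the pair as a random block, quantile normalization, median centring, filters on dim genes, every probe or the mean of probes, eBayes without a trend or with robust set, array weights, the arrays of 1 time only, other thresholds, each run alone and each replicate left out, and for time the replicate number or the run as a block. Cyclic loess, a spread set by time (arrayWeights with var.group), both of these together and the 10 h pairs 2 and 3 alone were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.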

Results

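Expression of 22180 genes was measured on 22 arrays of sorted fetal liver haematopoietic stem cells that had been cultured on Notch ligand-expressing stroma with or without gamma-secretase inhibitor (GSI). The groups were DMSO at 4 h (n = 7), GSI at 4 h (n = 7), DMSO at 10 h (n = 4) and GSI at 10 h (n = 4). Each DMSO culture had a GSI partner, which gave 7 pairs at 4 h and 4 pairs at 10 h. Changes are log2 fold changes of GSI minus DMSO unless stated otherwise, errors of changes are standard errors (SE), and errors of levels are SDs. The number of arrays limits the precision.

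The comparison at 4 h asks which genes respond to a short block of gamma-secretase, the enzyme that releases the active part of Notch. Hes1, the classical Notch target that encodes a transcriptional repressor, fell by 0.97 ± 0.088 on the log2 scale (n = 7 pairs, limma adjusted p = 0.00020). Its level (Entrez 15205, chromosome 16) was 8.42 ± 0.713 in DMSO and 7.44 ± 0.904 in GSI, a 1.96-fold decrease, and it was lower with GSI in 7 of 7 pairs. Hes1 was the only gene of 22180 to pass at 4 h, where 934 genes had an unadjusted p under 0.05 and 1109 would by chance. The count was 3 without pair 6, 148 within run 2 (2 pairs) and 1 within run 3.

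Other Notch targets did not pass at 4 h. Nrarp, a feedback inhibitor of Notch, differed by -0.10, Dtx1 by 0.10, Hey1 by -0.23, Heyl by -0.15 and Hes5 by -0.06, and the adjusted p was 0.999 for each. Averaged over all arrays, Dtx1 had a level of 4.96 (3.55 at its other probe) and Hes5 of 4.91 (4.86 at its other probe). The median value per array at 4 h was 5.03 to 5.12, so at such low signal a change could be missed. The receptor genes Notch1 and Notch3 differed by -0.03 and 0.11, and the growth regulator Myc by 0.08. Of the 16 measured Notch target genes, 1 fell, Hes1, both over all genes and adjusted over the list alone, and the other 15 did not pass. The mean of this list was -0.08 (camera adjusted p = 0.0695, and adjusted p = 0.419 with an estimated correlation). Without pair 7 the mean was -0.11 and the list passed (camera adjusted p = 0.0270). Hes1 is part of these means, and no mean without it is given. The ligand gene Dll4 had the smallest p of the 23 Notch receptor, ligand and modifier genes. It was lower in 7 of 7 pairs (-0.45 ± 0.096, adjusted p = 0.420), did not pass over all genes and fell when adjusted over the list alone. Early T-lineage genes had a mean of -0.01 (adjusted p = 0.676) and gamma-secretase subunits a mean of 0.01 (adjusted p = 0.983). The level of the early T-lineage list was also low, 4.86 in DMSO at 4 h.

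The 9 genes with the next smallest p at 4 h did not pass. Il12a, which encodes a subunit of interleukin 12, was 0.53 ± 0.087 higher in 7 of 7 pairs (adjusted p = 0.193), and the potassium channel gene Kcnk5 was 0.60 higher in 7 of 7. Slc7a8 (0.47), Cited2 (0.60), Nfil3 (0.61) and Prkcq (0.69) had higher values with GSI. H2-Q10 (-0.83), Itgal (-0.46) and Depp1 (-0.50) had lower values in every pair. H2-Q10 belongs to a family of near-identical class I histocompatibility genes, and its other probe differed by only -0.09. With the spread set by time, Il12a and H2-Q10 passed beside Hes1, each with an adjusted p of 0.0492.

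**Figure D1:**
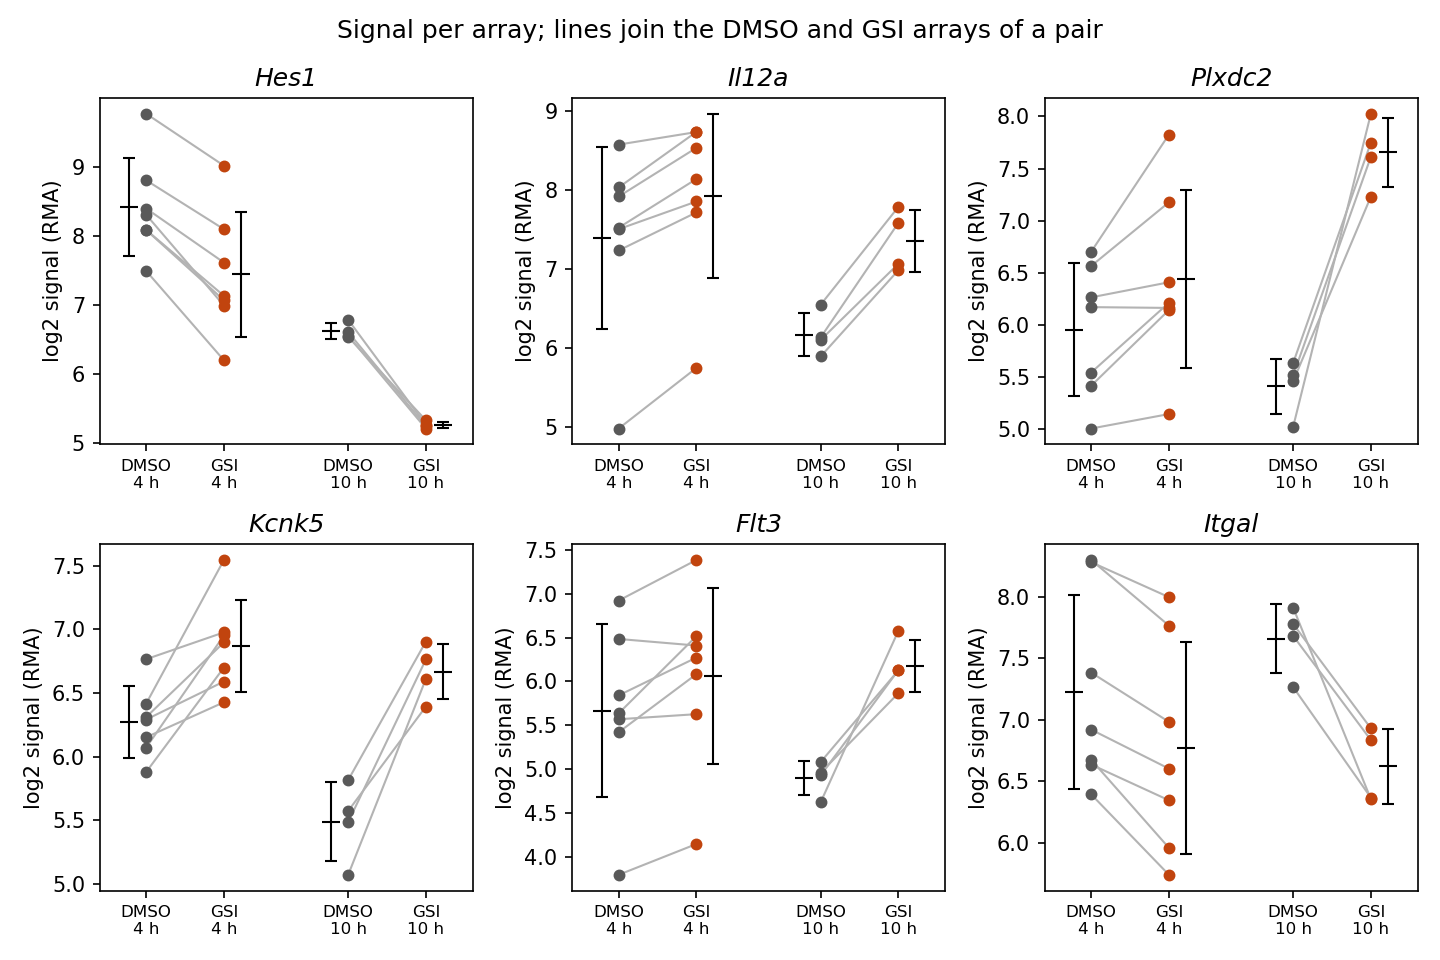
Log2 RMA signal of 6 genes on every array, grouped by treatment and time, with lines joining the DMSO and GSI arrays of a pair and black bars giving mean ± SD. Hes1 was lower with GSI in 7 of 7 pairs at 4 h and in 4 of 4 at 10 h, and Plxdc2 was 5.41 ± 0.267 in DMSO and 7.65 ± 0.331 in GSI at 10 h.

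Among the gene lists at 4 h, 10 of 26 passed with camera, 7 of them upward, and none passed with fry (lowest adjusted p = 0.398). Genes of cholesterol synthesis were higher with GSI in 15 of 16 cases (mean 0.15, camera adjusted p = 4.2e-06, and adjusted p = 0.419 with an estimated correlation). No member passed over all genes, and 4 rose when adjusted over the list alone: Fdps (0.23), Sqle (0.27), Lss (0.39) and Msmo1 (0.31), all enzymes of the sterol pathway. Inflammatory and NF-kB genes had a mean of 0.19 (17 of 19 positive, camera adjusted p = 0.00028, and adjusted p = 0.419 with an estimated correlation). The chemokine genes Ccl4 (0.75), Ccl3 (0.84) and Ccl2 (0.53) had the largest values there, and 1 of the 19 rose when adjusted over the list alone. The largest list mean was in pair 1 (0.574), where macrophage (0.824), neutrophil and monocyte (1.02) and OP9 stromal (0.954) markers were also highest. Amino acid and unfolded protein stress genes had a mean of 0.10 (19 of 21 positive, adjusted p = 0.0011, and adjusted p = 0.419 with an estimated correlation), with values of 0.33 for Sdf2l1 and 0.17 for the chaperone gene Hspa5; none passed adjusted over the list alone. The cholesterol, inflammatory and stress lists passed whichever pair was left out. Over all settings, however, the camera adjusted p reached 0.133 for the cholesterol list and 0.831 for the stress list. By pair, the stress mean was 0.243 and 0.296 in run 2, and 0.020, 0.039, 0.040 and -0.0086 in run 3. The inflammatory mean was 0.337 and 0.146 in run 2, and 0.358, -0.018, 0.044 and -0.076 in run 3.

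The other 7 lists that passed at 4 h each lost the call when a single pair was left out. Erythroid genes had a mean of -0.15 (15 of 17 negative, camera adjusted p = 0.0011, and adjusted p = 0.669 with an estimated correlation), with -0.39 for the band 3 gene Slc4a1 and -0.49 for the embryonic globin Hbb-bh1. Without pair 4 that mean was -0.07 (adjusted p = 0.177) and Slc4a1 was -0.21, and without pair 7 the mean was -0.08 and Hbb-bh1 -0.18. Megakaryocyte genes were positive in 15 of 15 cases (mean 0.15, adjusted p = 0.0015, and adjusted p = 0.419 with an estimated correlation), with 0.39 for Rab27b and 0.29 for Selp, and had a mean of 0.06 without pair 4. JAK-STAT feedback genes such as Socs1 (0.24) and Pim1 (0.33, -0.01 at its other probe, and 0.20 without pair 2) had a mean of 0.13 (adjusted p = 0.0166, and adjusted p = 0.419 with an estimated correlation), and 0.09 without pair 2. Stem cell genes had a mean of 0.07 (22 of 28 positive, adjusted p = 0.0205, and adjusted p = 0.676 with an estimated correlation). Hlf (0.38), Hoxa9 (0.34), Gata2 (0.29) and Prdm16 (0.24, -0.10 at its other probe, and 0.16 without pair 4), all transcription factor genes of stem cells, had the smallest p, and 1 of the 28 rose adjusted over the list alone. That list lost its call without pair 2 (0.06), pair 4 (0.05) or pair 7 (0.06).

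Mitosis genes had a mean of -0.03 at 4 h (adjusted p = 0.0205, and adjusted p = 0.710 with an estimated correlation), with -0.15 for the cyclin gene Ccna2, and lost the call without pair 2, 4, 6 or 7 (means -0.03, -0.03, -0.02 and -0.02). Macrophage markers had a mean of 0.10 (adjusted p = 0.0288, and adjusted p = 0.710 with an estimated correlation), with 0.37 for Adgre1 (0.17 without pair 1) and 0.26 for the complement gene C1qc. Their mean was -0.02 without pair 1, 0.08 without pair 2 and 0.09 without pair 4, and none of these passed; it was 0.15 without pair 5. Hepatocyte markers had a mean of -0.10 (adjusted p = 0.0438, and adjusted p = 0.774 with an estimated correlation), with -0.30 for Apoh (-0.19 without pair 5) and -0.37 for the fibrinogen gene Fgb (-0.15 without pair 7). The list mean was 0.04 without pair 7, -0.06 without pair 4 and -0.08 without pair 5, again without a call, and it was -0.19 without pair 1 and -0.17 without pair 3. No member of any list in this paragraph, or of the erythroid, megakaryocyte and JAK-STAT lists, passed adjusted over the list alone. Within runs, the erythroid mean was 0.19 in run 2 and -0.42 in run 3, and the hepatocyte mean was 0.19 in run 2 and -0.37 in run 3.

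The 15 lists besides the Notch targets that did not pass at 4 h included interferon response genes (mean 0.09, adjusted p = 0.0695), neutrophil and monocyte genes (0.11, adjusted p = 0.0695), immediate-early and stress genes (0.07, adjusted p = 0.0923), OP9 stromal markers (0.11, adjusted p = 0.183) and DNA replication genes (-0.02, adjusted p = 0.247). Genes of p53 and apoptosis had a mean of 0.05, mast cell genes -0.04, Myc and ribosome biogenesis genes 0.03, endothelial markers 0.03 and B-lineage genes -0.01. Genes of hypoxia and glycolysis, of cell cycle inhibition, and of Notch receptors, ligands and modifiers had means of 0.02, 0.02 and 0.01.

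At 10 h the comparison asks which genes respond to the longer block. Plxdc2, which encodes a membrane protein with a plexin-like domain, rose 4.75-fold (2.25 ± 0.193 on the log2 scale, n = 4 pairs, limma adjusted p = 4.7e-05), from 5.41 ± 0.267 to 7.65 ± 0.331. Hes1 fell by 1.36 ± 0.117 (2.56-fold, adjusted p = 4.7e-05), from 6.62 ± 0.113 to 5.27 ± 0.050. Il12a rose by 1.19 ± 0.115 (adjusted p = 0.00015), the cytokine receptor gene Flt3 of early progenitors by 1.28 ± 0.170 (adjusted p = 0.0037) and Kcnk5 by 1.18 ± 0.156 (adjusted p = 0.0037). Itgal, the alpha chain of the integrin LFA-1, fell by 1.04 ± 0.126 (adjusted p = 0.0017), and Sdr39u1 rose by 1.09 ± 0.132 (adjusted p = 0.0017). All of these moved the same way in 4 of 4 pairs.

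In total 148 of 22180 genes passed at 10 h, 123 higher and 25 lower with GSI (83.1% higher), and 3122 had an unadjusted p under 0.05. This count depends on the spread shared with the 4 h arrays: with the spread set by time 19 genes passed, all of them among the 148, and with the 10 h arrays alone 2 passed, Plxdc2 and Hes1. After cyclic loess normalization 64 passed, 40 higher and 24 lower (62.5% higher), and after quantile normalization 36 passed, 27 higher and 9 lower. The count was 48 without pair 1, 228 without pair 2 and 27 without pair 4. It was 0 within run 1, where limma gave adjusted p-values of at least 0.618 for the genes named above, and 15 within run 2.

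The other named rises at 10 h were Rnf19b (1.23), the ribosomal protein gene Rps15 (1.15), Tnip3 (1.15), which encodes an inhibitor of NF-kB signalling, Sft2d2 (1.08) and Rasgef1b (1.07). The other named falls were Fabp4, a fatty acid carrier (-2.05 ± 0.446, with an SD of 1.94 in GSI, and -1.18 without pair 4), Cd248, a marker of stromal cells (-1.33), Emp1 (-1.08, and -0.38 at its other probe), the oxidative stress gene Nqo1 (-1.002), Slc35d3 (-0.95), Mical1 (-0.86), Parvb (-0.83) and Gstp3 (-0.73). The adjusted p of these genes lay between 0.0135 and 0.0495, and none of them passed with the spread set by time. Each of these 13 also lost its call without pair 1 or without pair 4. The genes that passed with that setting were Plxdc2, Hes1, Il12a, Itgal, Sdr39u1, Flt3 and Kcnk5 and, chosen after their values were seen, Adgrl4 (0.71), Calcrl (0.53), Extl3 (0.96), Tmem141 (1.01), Snx2 (0.45), AU020206 (0.55), Csf3r (0.88), Afap1l1 (0.73), Zfp773 (1.02), Slc35b1 (0.50), Fchsd2 (0.70) and Rab2b (0.67).

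Stem cell genes rose as a group at 10 h. The list mean was 0.31 over 28 measured genes, 23 of them positive (camera adjusted p = 8.1e-10, and adjusted p = 0.240 with an estimated correlation). With fry this list passed (adjusted p = 0.0314), in a fit of all arrays that was not repeated with the spread set by time. The 4 other lists that camera called at 10 h did not pass with fry: OP9 stromal 0.366, cholesterol 0.197, stress 0.288 and JAK-STAT 0.173. Of the stem cell genes 5 rose and none fell over all genes, and 12 rose when adjusted over the list alone. Hoxa9 rose by 1.02 ± 0.179, Mecom by 0.82 ± 0.172 (0.63 at its other probe), Hlf by 0.73 ± 0.132 and Mllt3 by 0.54 ± 0.105, transcriptional regulators of stem cell self-renewal, each in 4 of 4 pairs and with an adjusted p between 0.0223 and 0.0436. None of these 4 passed with the spread set by time, or without pair 1 (0.78, 0.58, 0.66 and 0.45 in the same order). The fifth was Erg (0.58, adjusted p = 0.0495). The mean level of the list was 6.76 ± 0.198 in DMSO and 7.07 ± 0.192 in GSI. The list mean was 0.588 and 0.274 in the pairs of run 1 and 0.132 and 0.246 in those of run 2.

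**Figure D2:**
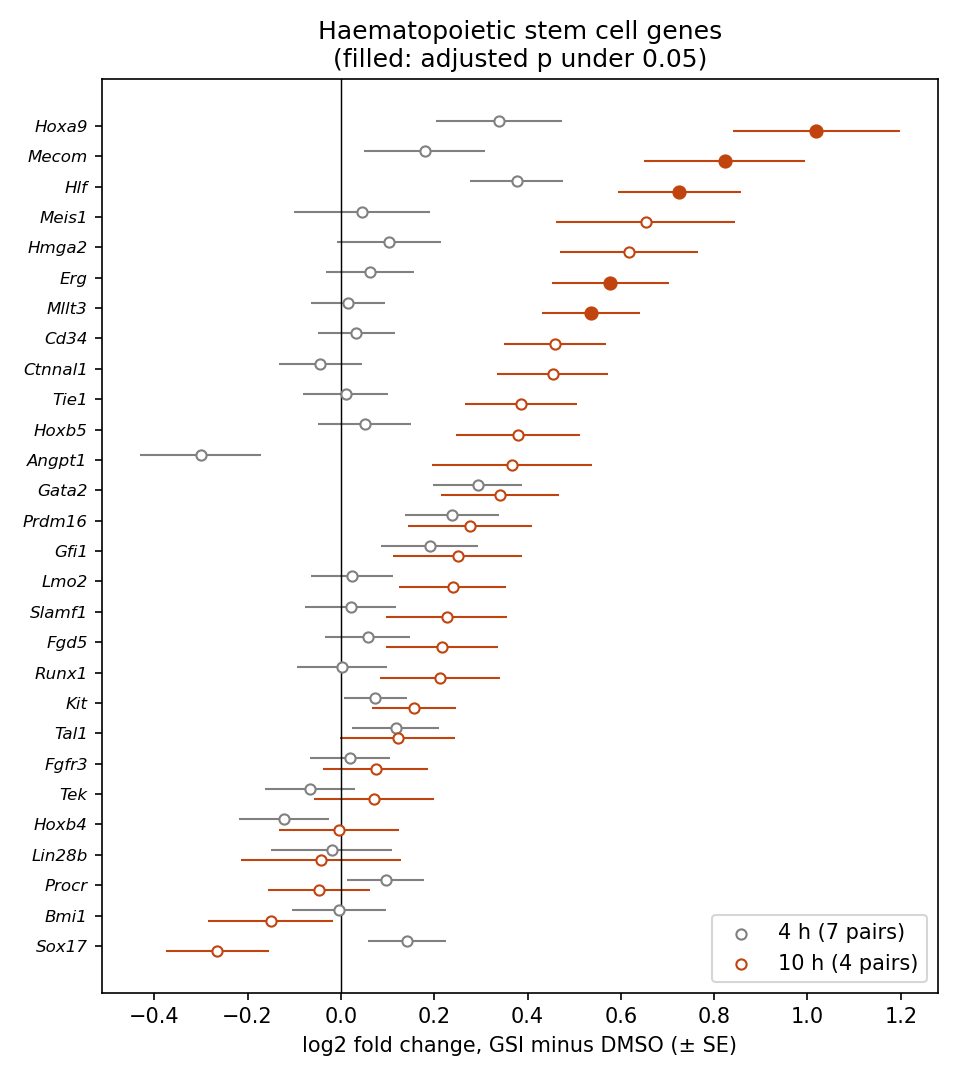
Log2 fold change of GSI minus DMSO (± SE) of the 28 measured stem cell genes at 4 h (grey, 7 pairs) and 10 h (red, 4 pairs), with filled points for adjusted p under 0.05. The list mean was 0.07 at 4 h and 0.31 at 10 h, and the 5 filled points are Hoxa9, Mecom, Hlf, Erg and Mllt3.

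Markers of OP9 stromal cells, the feeder layer, fell as a group at 10 h. Their mean was -0.38, and 21 of 23 were negative (camera adjusted p = 9.8e-05, and adjusted p = 0.610 with an estimated correlation). No member passed over all genes or adjusted over the list alone, with values of -1.10 for the collagen gene Col1a2 (-0.23 at its other probe, and -0.67 without pair 3), -0.70 for Thbs1 (-0.34 without pair 2), -0.50 for Ccn2 (-0.28 at its other probe) and -0.39 for Col6a2. Without pair 2 the mean was -0.25 and did not pass (adjusted p = 0.0522), and without pair 1 it was -0.57. The mean was 0.208 and -0.754 in the pairs of run 1 and -0.673 and -0.294 in those of run 2.

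The 3 other lists that passed at 10 h moved upward. Cholesterol synthesis genes had a mean of 0.15 (14 of 16 positive, camera adjusted p = 0.0059, and adjusted p = 0.610 with an estimated correlation); 2 rose when adjusted over the list alone, Sc5d (0.51) and Srebf2 (0.34), which encodes the transcription factor that drives the pathway. This mean was 0.06 after cyclic loess, 0.07 after quantile normalization and 0.12 without pair 3, and none of these passed. Amino acid and unfolded protein stress genes had a mean of 0.11 (adjusted p = 0.0222, and adjusted p = 0.610 with an estimated correlation). Herpud1, a gene of protein degradation at the endoplasmic reticulum, rose by 0.67 over all genes (not without pair 1, 3 or 4, at 0.71, 0.61 and 0.55), and 6 members rose and 1 fell adjusted over the list alone. The list mean was 0.17 without pair 2. The list did not pass without pair 1 (0.08) or pair 4 (0.07), or after cyclic loess (0.03) or quantile normalization (0.05). JAK-STAT feedback genes had a mean of 0.30 (9 of 11 positive, adjusted p = 0.0222, and adjusted p = 0.610 with an estimated correlation). Cish, a cytokine-induced inhibitor, rose by 0.71 (0.15 at its other probe, and without a call when pair 4 was left out) and Socs2 had a value of 1.83 (0.21 at its other probe, adjusted p = 0.117), which was 0.26 within run 1 and 3.40 within run 2, and 1.054 without pair 4; 2 members rose adjusted over the list alone. That list did not pass without pair 2 (0.32) or pair 3 (0.21), or after cyclic loess (0.24) or quantile normalization (0.25). The JAK-STAT mean was -0.106 and 0.258 in the pairs of run 1 and 0.578 and 0.488 in those of run 2.

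Notch target genes other than Hes1 did not pass at 10 h. Nrarp differed by -0.25 (adjusted p = 0.521, from -0.36 without pair 1 to -0.12 without pair 4), Dtx1 by 0.05, Hey1 by 0.0014, Heyl by 0.07, Hes5 by -0.05, Notch1 by 0.17, Notch3 by 0.12 and Myc by -0.06. The mean of the 16 measured targets was -0.11 (camera adjusted p = 0.373, with means of -0.15 without pair 1 and -0.07 without pair 4). Of them 1 fell, Hes1, over all genes and adjusted over the list alone. Mfng, which encodes a glycosyltransferase that modifies Notch, rose by 0.74 (adjusted p = 0.0495), while its list of Notch receptors, ligands and modifiers had a mean of 0.07 (adjusted p = 0.125), with -0.56 for Jag1 and -0.30 for Dll4. Gamma-secretase subunits had a mean of 0.16 (adjusted p = 0.216), with 0.40 for Psenen (0.75 at its other probe) and 0.36 for Ncstn, and 3 of 6 rose adjusted over the list alone.

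Lists that did not pass at 10 h held 4 more genes that did. Csf3r, the receptor for granulocyte colony-stimulating factor, rose by 0.88 in a neutrophil and monocyte list with a mean of -0.17. Fli1 rose by 0.56 in a megakaryocyte list with a mean of -0.02. Bcl2l11, which encodes the cell death protein Bim, fell by 0.71 in a p53 and apoptosis list with a mean of -0.05. Dusp6, a phosphatase that restrains ERK, fell by 0.44 (-0.11 at its other probe) in an immediate-early list with a mean of -0.02. Erythroid genes had a mean of -0.18 (16 of 17 negative, camera adjusted p = 0.0851), mast cell genes -0.17 and macrophage markers -0.17. Interferon response genes had -0.09, inflammatory and NF-kB genes -0.08, early T-lineage genes -0.04 and DNA replication genes 0.04. By pair, the interferon mean was -0.615 and -0.295 in run 1, and 0.327 and 0.223 in run 2. The inflammatory mean was -0.401 and -0.325 in run 1, and 0.237 and 0.164 in run 2, so these means hide opposite signs. The means of the hypoxia, B-lineage, cell cycle inhibitor, hepatocyte, mitosis and endothelial lists were 0.03, -0.02, 0.02, -0.02, 0.0076 and -0.03, and that of the Myc and ribosome biogenesis list was 0.00056.

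**Figure D3:**
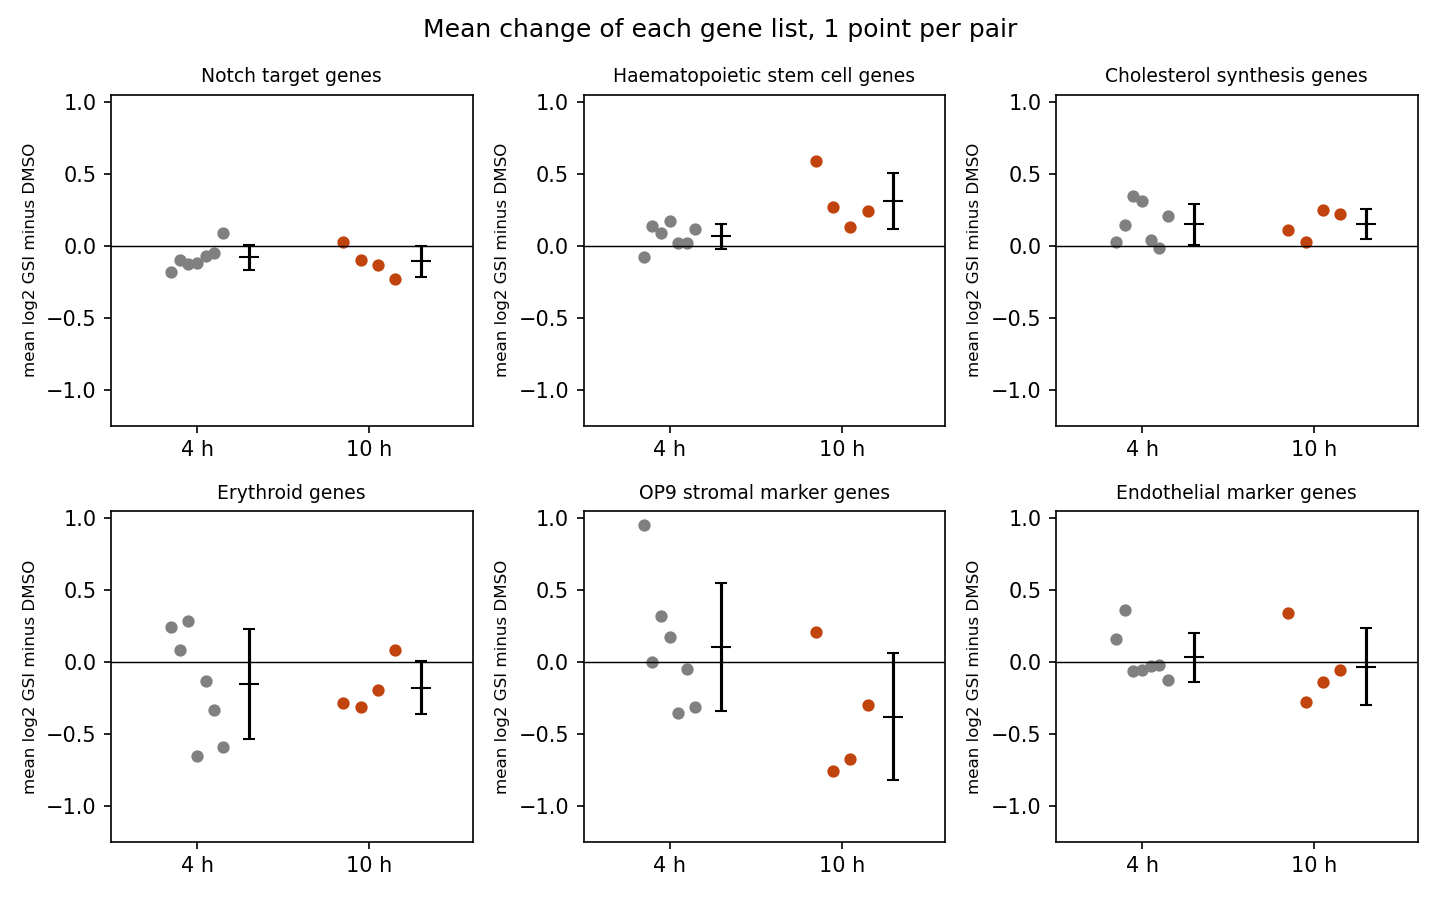
Mean log2 difference of GSI minus DMSO over the measured genes of 6 lists, with 1 point per pair at 4 h (grey, 7 pairs) and 10 h (red, 4 pairs) and black bars giving mean ± SD over pairs. At 10 h the stem cell list lies between 0.132 and 0.588 in the 4 pairs and the OP9 stromal list between -0.754 and 0.208.

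Averaged over both times with equal weight, 71 genes passed, 59 higher and 12 lower, and 60 of them were among the 148 at 10 h. The genes of this paragraph outside the Notch set were chosen after their values were seen. Hes1 fell by 1.16 ± 0.073 (limma adjusted p = 9.9e-07, lower in 11 of 11 pairs) and Itgal by 0.75 (lower in 11 of 11). Il12a rose by 0.86 ± 0.072 (adjusted p = 3.2e-05), Kcnk5 by 0.89, Tnip3 by 0.88 and Slc7a8 by 0.48, each higher in 11 of 11 pairs. Plxdc2 (1.37), Flt3 (0.84), Prkcq (0.75), Hoxa9 (0.68), Cited2 (0.64), Hlf (0.55) and Adgrl4 (0.42) rose in 10 of 11. The other Notch genes did not pass, with Nrarp at -0.17, Dtx1 0.08, Hey1 -0.11, Heyl -0.04, Hes5 -0.06, Notch1 0.07, Notch3 0.12 and Myc 0.0083. Lists that passed with camera were stem cell genes (0.19, camera adjusted p = 6.0e-10), cholesterol synthesis (0.15, 16 of 16 positive, 3.4e-06), amino acid and unfolded protein stress (0.10), JAK-STAT feedback (0.22), erythroid genes (-0.17, 16 of 17 negative) and OP9 stromal markers (-0.14, -0.21 without 4 h pair 1, -0.23 without 10 h pair 1, and not without 4 h pair 5 or 7 or 10 h pair 2 or 3, at -0.10, -0.10, -0.07 and -0.09). With an estimated correlation none of these 6 passed, with adjusted p-values of 0.206, 0.206, 0.361, 0.206, 0.636 and 0.762 in the same order. With fry the stem cell (adjusted p = 0.0339), cholesterol (0.0437) and JAK-STAT (0.0437) lists passed and the stress (0.101), erythroid (0.447) and OP9 stromal (0.677) lists did not. The Notch target list (mean -0.09) passed with fry (adjusted p = 0.0437) and not with camera (adjusted p = 0.212). Hes1 is part of that mean, and no mean without it is given. Without the pair block the cholesterol (adjusted p = 0.0811), erythroid (0.163) and OP9 stromal lists (0.182) did not pass, nor did the erythroid (0.0984) and OP9 lists (0.148) with the pair as a random block.  The count was 40, 39, 35 and 20 without 4 h pair 2, 3, 4 or 7 and 136, 109 and 40 without 10 h pair 2, 3 or 4; it was 36 after quantile normalization (69.4% higher against 83.1%) and 35 with the spread set by time.

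Whether the effect of GSI differed between 10 h and 4 h was tested directly. Plxdc2 differed by 1.76 (0.49 at 4 h), Zfp773 by 1.32 (-0.30 at 4 h), Sdr39u1 by 1.12 (-0.03 at 4 h) and the adhesion receptor gene Adgrl4 by 0.59 (0.12 at 4 h), each with a limma adjusted p of 0.0306. Those 4 were the only genes to pass, 2075 had an unadjusted p under 0.05, and Tmem141, the fifth by p, did not pass (1.01, adjusted p = 0.0980). The difference for Hes1 was -0.38 and did not pass (adjusted p = 0.452), nor did those for Nrarp (-0.15), Dtx1 (-0.04), Hey1 (0.23), Heyl (0.22), Hes5 (0.01), Notch1 (0.20), Notch3 (0.0082) and Myc (-0.14). Stem cell genes had a higher effect at 10 h (0.24, adjusted p = 5.9e-06, and adjusted p = 0.784 with an estimated correlation, and 0.148 without 10 h pair 1), and OP9 stromal markers (-0.48, adjusted p = 2.1e-05, and adjusted p = 0.841 with an estimated correlation) and macrophage markers (-0.27, adjusted p = 0.0160, and adjusted p = 0.841 with an estimated correlation) a lower one. With fry none of the 26 lists passed (lowest adjusted p = 0.508). The macrophage list did not pass without 4 h pair 1 (-0.15) or 10 h pair 1 (-0.25) or 2 (-0.18). No gene passed with the spread set by time. The count was 0 without 4 h pair 1, 4, 5, 6 or 7, 1 without 4 h pair 2 or 10 h pair 1, 2 or 4, and 7 without 10 h pair 3. Of the 148 genes called at 10 h, 118 (79.7%) had the same sign at 4 h, with a median absolute change of 0.09 at 4 h and 0.64 at 10 h. The share over all genes is not given. Over all genes the changes at both times had a Pearson r of 0.123, and the median SE at 4 h was 0.089. The 148 were picked by their 10 h values, so the larger size there is partly built in.

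The comparison of 10 h with 4 h in DMSO asks what the longer culture changed. The deposited values of all genes had a median difference of -0.41, which quantile normalization moved to 0.04, so values here are given relative to that median. The erythroid carbonic anhydrase gene Car1 was 3.48 higher at 10 h, the acute phase gene Saa3 3.13, the chemokine gene Ccl22 2.89, the mucin gene Muc13 2.81 and Plac8 2.38. Ces2g (2.25), Gdf3 (2.21), Pnp2 (2.13), Asb17 (2.11) and Zfp992 (2.10) were the next largest rises. Sema6a was -3.56, the transcription factor gene Maf -3.46, the neuropeptide gene Gal -3.42, the selenoprotein gene Selenop -3.30, the stress gene Gadd45b -3.28, Errfi1 -3.24, the fibrinogen gene Fgg -3.19, Eml1 -3.18, the basement membrane gene Nid1 -3.13 and the transthyretin gene Ttr -3.09. All 20 passed in the deposited values and after quantile normalization.

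With the deposited values 13348 genes differed by limma between the times in DMSO, 464 higher and 12884 lower at 10 h (3.48% higher). After quantile normalization it was 7560, with 55.1% higher. In GSI 14895 differed, 470 higher and 14425 lower, and 8197 after quantile normalization, with 56.4% higher. No run holds both times and the value distributions of both times differed, so time cannot be told apart from run or processing.

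Immediate-early and stress genes were lower at 10 h in DMSO (mean -1.64 relative to the median of all genes, 25 of 27 fell over all genes and adjusted over the list alone, camera adjusted p = 7.3e-06). So were endothelial markers (-2.11, 14 of 14 fell, adjusted p = 0.0031), p53 and apoptosis genes (-1.11, 17 of 19 fell, adjusted p = 0.0061) and Notch receptors, ligands and modifiers (-0.70, 21 of 23 fell, adjusted p = 0.0070). Fall counts are from the deposited values, in which 12884 of 22180 genes fell. DNA replication genes (0.49, adjusted p = 5.1e-10), erythroid genes (0.70, adjusted p = 7.1e-09) and Myc and ribosome biogenesis genes (0.41, adjusted p = 3.0e-07) were relatively higher. All 7 kept direction and call after quantile normalization, and the erythroid list did not pass after median centring (adjusted p = 0.173). Interferon response genes (0.49, adjusted p = 1.2e-06, and 0.30 without 10 h pair 3 or 4 and 0.77 without 4 h pair 1) did not (adjusted p = 0.0997), nor after median centring (0.967), and neutrophil and monocyte genes passed upward (adjusted p = 0.0320) although their relative mean was -0.02, and not after quantile normalization (adjusted p = 0.922), nor without 4 h pair 1 or 6 (-0.14 and -0.13) or 10 h pair 1 or 2 (-0.10 and -0.16). The lowest adjusted p with an estimated correlation was 0.524 in DMSO. With fry, which tests deposited values against 0, the 5 lists higher by camera did not pass (DNA replication 0.495, erythroid 0.338, Myc 0.968, interferon 0.984, neutrophil and monocyte 0.0663), and the 4 lower ones did.

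After quantile normalization 6 further lists passed in DMSO, with means given without subtracting the median of 0.04. Hepatocyte markers (-1.71, adjusted p = 7.1e-05), OP9 stromal markers (-0.75, adjusted p = 0.0037), macrophage markers (-0.76, adjusted p = 0.0129), inflammatory and NF-kB genes (-0.71, adjusted p = 0.0028) and stem cell genes (-0.36, adjusted p = 0.0063) were lower at 10 h, and mitosis genes (0.21, adjusted p = 0.0394) were higher. In deposited values the endothelial list had a level of 9.09 ± 0.852 at 4 h and 6.57 ± 0.651 at 10 h, the hepatocyte list 7.25 ± 1.16 and 4.98 ± 0.192, and the stem cell list 7.73 ± 0.230 and 6.76 ± 0.198. In GSI 8 lists passed in the deposited values, with immediate-early, p53, endothelial and OP9 stromal genes lower and DNA replication (0.56), erythroid (0.68), Myc (0.39) and interferon genes (0.32) higher at 10 h relative to the median of all genes. The erythroid list did not pass there after median centring (adjusted p = 0.0821), nor did the interferon list (0.487), which had a relative mean of -0.0049 without 10 h pair 3. The lowest adjusted p with an estimated correlation there was 0.180, and with fry the 4 lower lists passed and the 4 higher ones did not (lowest adjusted p = 0.262).

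**Figure D4:**
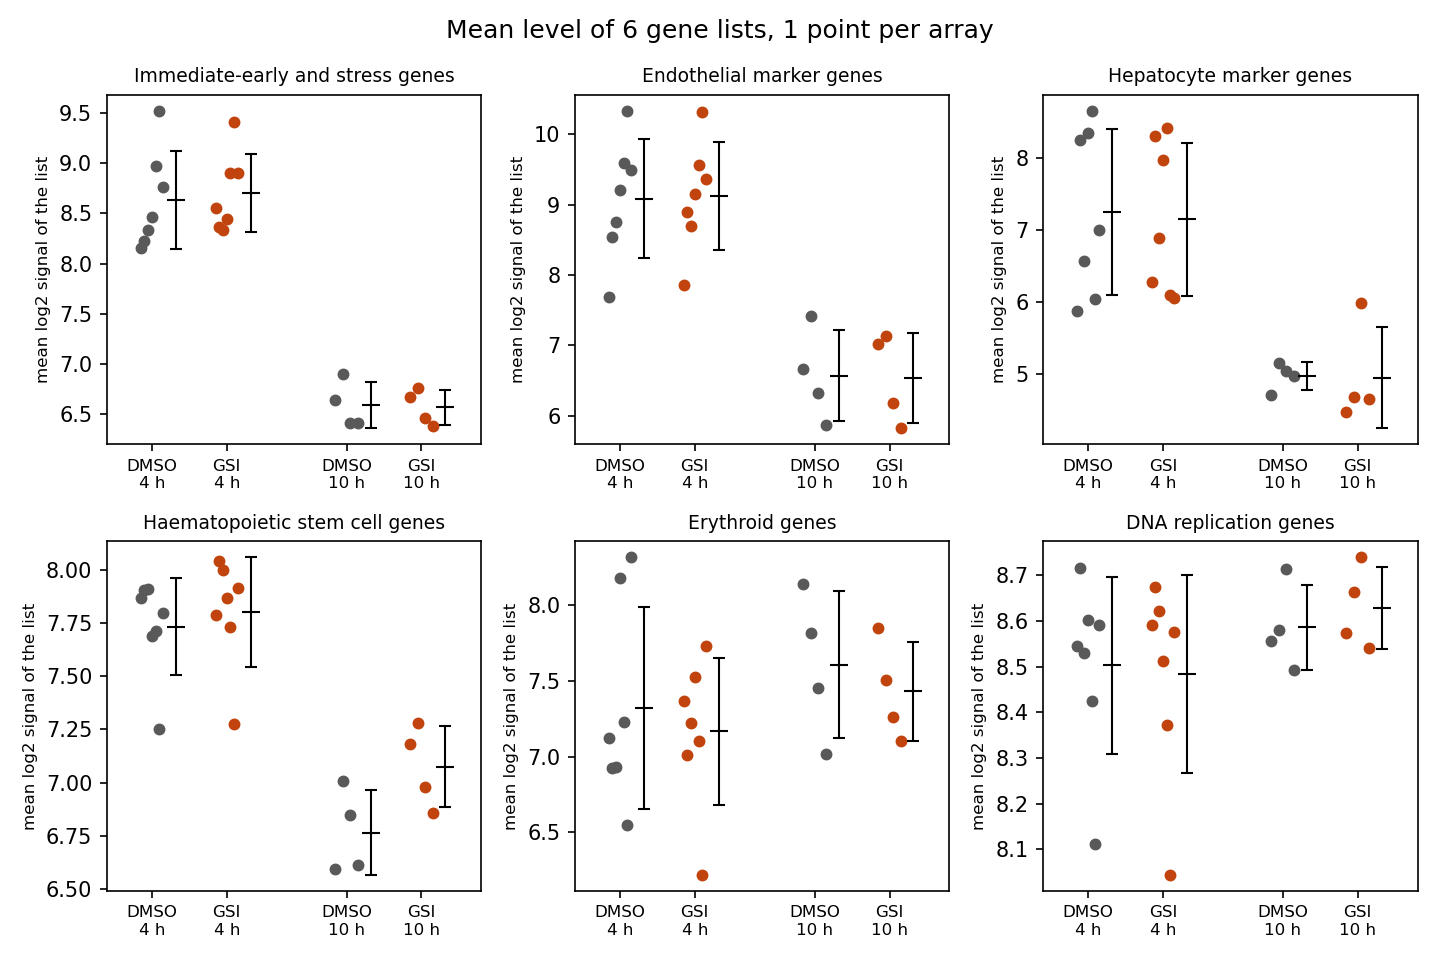
Mean deposited log2 signal of 6 gene lists, with 1 point per array by treatment and time and black bars giving mean ± SD. The endothelial list was at 9.09 ± 0.852 in DMSO at 4 h and 6.57 ± 0.651 at 10 h, with the median of all genes 0.41 lower at 10 h.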

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

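The test for fewer cells of other types in the GSI sorts was chosen after the result was seen, as were cyclic loess normalization, the spread set by time, both together, pairs 2 and 3 alone, and the 10 h arrays alone as a test of single genes. Pairs that stood apart were sought in 98 sets of 4 or 7 pair differences with a test that chance meets in about 1 in 20 groups, and 6 were found, which is what chance can give. At 4 h, Nfil3 in pair 2 was 1.49 against 0.35 to 0.56 in the other pairs. The interferon list in pair 4 was 0.51 against -0.10 to 0.15. The macrophage list in pair 1 was 0.82 against -0.23 to 0.21. At 10 h, Itgal in pair 2 was -1.55 against -0.90 to -0.85, Hey1 in pair 2 was -0.37 against 0.09 to 0.16, and the hepatocyte list in pair 3 was 0.95 against -0.48 to -0.24.

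The effect of GSI differed between 10 h and 4 h for Plxdc2 by 1.76, for Zfp773 by 1.32, for Sdr39u1 by 1.12 and for Adgrl4 by 0.59, and for the stem cell list by 0.24, the OP9 stromal list by -0.48 and the macrophage list by -0.27, each by a test of the difference. With an estimated correlation none of these 3 lists passed (adjusted p = 0.784, 0.841 and 0.841). For the gene count chance is not excluded, but regroupings cannot judge it. Of 100 regroupings that swap treatments within pairs, the real one included, 5 gave at least the real 4 genes, and the highest other gave 37. Swapping pairs of only 1 time turns an effect shared by both times into a difference between them. These counts therefore do not show what chance alone gives. For the other counts, chance regrouping is unlikely at 4 h (1 gene, highest other 0, of 64 regroupings) and over both times (71, highest other 27, of 100). In each of these 1 regrouping, the real one, reached the count, but so few regroupings cannot exclude chance. For time the real grouping also gave the most genes, in DMSO (13348, highest other 1554) and in GSI (14895, highest other 1), but the offset of -0.41 between the values of both times in DMSO and the runs go with the real grouping, so nothing about time is drawn from this. At 10 h the 8 possible regroupings are too few to judge (148, highest other 1).

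The first pattern weighed is the 148 genes called at 10 h, 83.1% of them higher. A spread borrowed from the less variable 4 h arrays may account for part of the count: 19 genes passed with the spread set by time, although it was known before this test that the 10 h arrays alone gave 2. Sizes stayed the same there, so calls ended by a larger SE (median 0.121 before and 0.139 after for the 106 higher genes that ended) and a largest p called that went from 0.00033 to 0.000038. Simulated arrays without any change and with the spread of each time gave 8 calls. Signal differences that depend on expression level between the arrays of a pair may account for part of the excess of higher genes, since 64 genes passed after cyclic loess with 62.5% higher. The 83 higher genes whose calls ended there went from a median of 0.57 to 0.47 at a median SE of 0.115 in both, while the largest p called went from 0.00033 to 0.00014. Whether pairs 1 and 4, whose DMSO arrays had lower upper quartiles (6.35 and 6.30 against 6.48 and 6.47), made the pattern stays open: of the genes with an unadjusted p under 0.01 there, 63.2% had the same sign in pairs 2 and 3, against 54.0% of all genes.

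Of the 19 genes, Plxdc2 and Hes1 passed with the 10 h arrays alone (limma adjusted p = 0.0321 and 0.0389). This argues against a borrowed spread for Hes1, which was named beforehand, while Plxdc2 was picked by this outcome. Only these 2 of the 19 passed in that fit, which has fewer arrays, so it cannot decide for the other 17. Sizes were the same there. Compared with the spread set by time, the SE went from 0.186 to 0.156 for Kcnk5 and from 0.077 to 0.094 for Adgrl4. After cyclic loess with the spread set by time 11 of the 19 passed (median size 0.96 before and 0.89 after). The others kept direction with smaller sizes, from 0.88 to 0.79 for Csf3r and from 0.50 to 0.41 for Slc35b1. Loess thus took away only part of their sizes, and level-dependent signal stays open for their calls. Plxdc2 (2.18), Hes1 (-1.45), Il12a (1.09), Itgal (-1.12) and Adgrl4 (0.63) passed after loess with limma adjusted p-values of at most 0.0019. With pairs 2 and 3 alone beside the 4 h arrays (2.11, -1.36, 1.10, -1.20 and 0.55) they passed with at most 0.0239. For Hes1 this argues against level-dependent signal and against pairs 1 and 4 as the whole cause. All but Hes1 were picked because they passed in these fits, so nothing is drawn from this for them. Hes1 passed the paired test of GSI against DMSO at both times. For the other genes a response to the inhibitor, which the design names, remains open.

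The second pattern is the higher stem cell list at 10 h. Values argue against the expression level of its genes as the whole cause. The list mean of 0.31 lay at percentile 100 of 10000 random lists matched on level (mean 0.06), and at 100, 100, 97.2 and 95.6 within the 4 pairs. In pair 4 the matched lists had a mean of 0.117 against 0.246 for the stem cell list, so level may account for part there. Random lists leave out the correlation between the genes of the list, so these percentiles may be too high. Of the 8 regroupings that swap treatments within the 4 pairs, the real one gave the largest list mean (0.31, highest other 0.24). So few regroupings cannot judge chance. Whether the GSI sorts held fewer cells of other types cannot be told apart from a change in the stem cells: over the 4 pairs the means of 8 of 8 lists of other types lay below 0, 5 of them by more than their SE and none above. These lists fell in 23 of 32 cases, 8 of 8 in pair 2 but 4 of 8 in pair 1, where the stem cell list rose most. The SLAM LSK gate is meant to remove such cells, but how far it did was not tested. A response of the stem cells to the inhibitor, which the design names, stays open and untested.

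The third pattern is the lower Dll4 at 4 h (-0.45, in 7 of 7 pairs, not past the threshold). Endothelial cells in the sort could carry it, since Dll4 is a Notch ligand of arteries. The SLAM LSK gate is meant to remove them, but how far it did was not tested. The endothelial list had a mean level of 9.09 in DMSO at 4 h, against array medians of 5.03 to 5.12. Which cells of the sort carried these genes was not tested, so this level does not show endothelial cells. The Dll4 change and the DMSO level of the endothelial list had a Pearson r of -0.69 over 7 pairs. This lies between the bounds set beforehand (-0.7 and -0.3), so endothelial cells cannot be told apart from a change in the stem cells. The DMSO arrays enter both terms, and the Dll4 level followed the list there (r = 0.990). Part of a negative r may come from that alone, which the bounds did not allow for. Within runs, a test chosen after the result was seen, r was 0.067 (exact p = 0.938), and in run 3 it ran from -0.914 to 0.997 when 1 of its 4 pairs was left out, so these pairs are too few to decide. The endothelial list itself did not pass (mean 0.03, adjusted p = 0.611).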

How the results depend on the processing

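Cyclic loess, the spread set by time and the 10 h pairs 2 and 3 alone were chosen after seeing the data; the other settings were planned. Of 3417 alternative values of 172 single genes and lists, 2936 kept direction and side of the threshold, 412 lost the call, 28 gained it and 41 changed sign, 27 of these with neither value called. Unless the setting itself shows it (fewer arrays or genes, another threshold), the cause was not tested. Signal over background was not analysed here, so no limit of detection is given. Counts of genes at 10 h (148) were 0 with no replicate block, 41 with the pair as a random block, 36 after quantile normalization, 64 after cyclic loess, 285 without genes under the median level, 22 with every probe on its own, 91 without the eBayes trend, 25 with array weights, 2 with only the arrays of that time, 19 with the spread set by time, 408 at an adjusted p under 0.10, 261 at an unadjusted p under 0.05 and at least 1.5-fold, 0 within run 1, 15 within run 2 and 9 with 10 h pairs 2 and 3 only; leaving out each replicate gave 27 to 228. At 4 h (1) they were 0 with no replicate block, 3 with array weights, 2 with only the arrays of that time, 3 with the spread set by time, 25 at an unadjusted p under 0.05 and at least 1.5-fold and 148 within run 2; leaving out each replicate gave 1 to 3. Over both times (71) they were 2 with no replicate block, 16 with the pair as a random block, 36 after quantile normalization, 113 without genes in the lowest tertile of level, 162 without genes under the median level, 8 with every probe on its own, 35 with the spread set by time, 230 at an adjusted p under 0.10 and 38 at an unadjusted p under 0.05 and at least 1.5-fold; leaving out each replicate gave 20 to 136. For the difference between times (4) they were 0 with no replicate block, 0 with a random block, 0 after quantile normalization, 0 with every probe on its own, 0 with array weights, 0 with the spread set by time, 2 after cyclic loess and 301 at an unadjusted p under 0.05 and at least 1.5-fold; leaving out each replicate gave 0 to 7, and limma gave 2075 genes at an unadjusted p under 0.05. For time in DMSO (13348) they were 7560 after quantile normalization, 7142 without genes under the median level, 20870 with every probe on its own and 8008 at an unadjusted p under 0.05 and at least 1.5-fold; for GSI (14895) they were 8197, 7116, 23855 and 7853. The Notch target list at 4 h (-0.08) passed with classical targets only (-0.13, camera adjusted p = 0.035), which include Hes1. Its adjusted p ran from 0.027 to 0.599 over all alternatives, and its mean from -0.11 to -0.061 when each replicate was left out.

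Values that changed sign at 4 h were, within run 2, Epor 0.16, Hemgn 0.28, Slc4a1 0.053, Vtn 0.051, Heyl 0.093, the erythroid list 0.19 and the hepatocyte list 0.19, and, within run 3, Atf3 -0.024, Hes5 0.23, Notch1 0.030 and the macrophage list -0.054. Leaving out each replicate gave -0.19 to 0.037 for the hepatocyte list, -0.021 to 0.15 for the macrophage list and -0.18 to 0.056 for Hes5. At 10 h Hes5 was 0.077 as the mean of all probes, 0.077 with array weights, 0.56 within run 1, 0.41 with 10 h pairs 2 and 3 only and -0.31 to 0.41 with each replicate left out. Hey1 was -0.013 with array weights, -0.14 within run 1, -0.049 after cyclic loess, -0.13 with 10 h pairs 2 and 3 only and -0.053 to 0.12 with each replicate left out. Within run 2 Dtx1 was -0.091, Heyl -0.028 and Notch3 -0.066; Heyl ran from -0.083 to 0.16 with each replicate left out, and Notch1 was -0.13 with 10 h pairs 2 and 3 only. For time, relative to the median of all genes, the neutrophil and monocyte list in DMSO was 0.11 after quantile normalization (0.15 without subtracting the median), 0.068 with the shared replicate number as a block and -0.16 to 0.13 with each replicate left out, and the interferon list in GSI ran from -0.0049 to 0.68. The stem cell list at 10 h kept its call in all 15 alternatives of the fit (0.19 to 0.43, adjusted p 1.8e-10 to 0.00046), though not with an estimated correlation.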

Other observations

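The relations with the endothelial list here were chosen after the levels were seen. Several gene lists, markers of other cell types among them, differed between the 4 h cultures more than GSI moved them. The endothelial list, with genes of vessel walls, ran from 7.69 to 10.3 in the 7 DMSO arrays at 4 h. It was 7.69 in run 1, 8.53 and 8.76 in run 2 and 9.21 to 10.3 in run 3, so its level followed the run. Interferon response genes had levels from 6.71 to 9.20 in the same arrays, with 9.20 in pair 1, 7.80 in pair 4 and 8.30 in pair 5 and at most 6.91 in the other pairs. Hepatocyte markers ran from 5.88 to 8.66 and cholesterol synthesis genes from 7.04 to 8.86.

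Over the 7 pairs 4 relations with the DMSO level of the endothelial list were computed, with exact 2-sided permutation tests. The level of Dll4 rose with it (r = 0.990, exact p = 0.00060, adjusted p = 0.0024; rho = 1, exact p = 0.00040, adjusted p = 0.0016). The change of Hes1 with GSI was smaller where it was high (r = 0.838, exact p = 0.0157, adjusted p = 0.0313; rho = 0.857, exact p = 0.0238, adjusted p = 0.0476). The stem cell list was lower there by r (r = -0.793, exact p = 0.0329, adjusted p = 0.0439), not by rank (rho = -0.750, exact p = 0.0663, adjusted p = 0.0884). The change of Dll4 did not pass (r = -0.693, exact p = 0.0810, adjusted p = 0.0810, and rho = -0.679, exact p = 0.110, adjusted p = 0.110). Both changes are taken against the same DMSO arrays that give the endothelial level, so part of these 2 relations may come from that. Without the 2 pairs farthest from the median the r values were 0.966, 0.801, -0.804 and -0.752. The endothelial level follows the run, so the 4 relations were also tested within runs, with the run as a block and with the 48 orders of pairs within runs. The level of Dll4 rose with the endothelial list within runs too (slope 1.599 ± 0.238, adjusted p = 0.0270; r = 0.968, exact p = 0.0208, adjusted p = 0.0833), with r in run 3 of at least 0.942 whichever pair was left out. The stem cell list did not pass (r = -0.877, block adjusted p = 0.101, exact adjusted p = 0.333), and its r in run 3 went from -0.894 to 0.446 without 1 of the 4 pairs. The changes of Hes1 (r = 0.252, block adjusted p = 0.911) and of Dll4 (r = 0.067, block adjusted p = 0.914) did not pass within runs. Differences between runs stay open for these 3 relations.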
